A study of Mus musculus with 2 samples.

How the data were processed

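The samples were 2 total RNA libraries from the adrenal glands of 4-day-old male B6CASTF1/J mice, 1 group with 2 biological replicates per the labels. The labels give different male numbers in the sample characteristics, while a description shared by both samples repeats one of these numbers, and both carry one donor label. They were treated as different animals, as their biosample labels differ. Per the labels' protocols, RNA was purified with a tissue RNA kit and libraries were made with a directional kit from 300 ng of RNA with ERCC spike-ins. For each library the authors deposited 3 tables, made per library against mm10 and GENCODE release M21, per the descriptions deposited with the files. The gene table and the first transcript table were derived from an alignment to the transcriptome and have the column layout that RSEM writes. The second transcript table was derived from the reads and an index without an alignment, has the layout that kallisto writes, and is called the alignment-free table. The programs, their versions and settings are not given in the sources used here.

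The deposited expected counts, per the file headers, are estimates that share reads among transcripts and need not be whole. The TPM values deposited by the authors scale counts by effective length to a fixed total per library. Short RNAs therefore weigh heavily in TPM, and a library with more of them shows lower TPM for messenger RNAs. The alignment-based tables use an effective length of the length minus 99 bases for long transcripts, and the alignment-free tables the length minus 326.1 and 324.1 bases for replicates 1 and 2, as read from the deposited length columns. The percent of a gene's TPM taken by each transcript was computed here from the deposited TPM. Counts were rounded to whole numbers before any count method. Spike-ins took 1.06% of all counts in each library, and 26248 rows with a number in place of a gene identifier held 3 and 2 counts and were left out, as were spike-ins, except where spike-in counts set the library size. The tables held 55536 annotated genes, all found in the annotation, which gave symbols and coordinates (start and end counted from 1). Where a list's symbol had more than 1 gene, as for Rmrp, the one of higher mean TPM was used. The list members Ahsp and Rn7sl1 were not found. Alignment-free values were summed per gene, and 86 genes had no transcript there. Identical or similar copies (the globin pair Hba-a1 and Hba-a2, Rn7s1 and Rn7s2, small nuclear RNAs, nuclear copies of mitochondrial genes, Cyp11b1 and Cyp11b2) can exchange reads in both kinds of table. Whether counting used the strand is not given in the sources used here, so antisense overlaps are uncertain.

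Levels are mean TPM ± SD over the 2 libraries, and detection is a mean TPM of 1 or more. Library sizes were set with TMM in edgeR 4.0.16 (R 4.3.3) after filterByExpr, which kept 18160 genes. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept only. Each kept gene's counts in the 2 libraries were compared with an exact two-sided binomial test (the smaller tail doubled) against the TMM sizes. P was adjusted by Benjamini-Hochberg over all 18160 genes, with a threshold of 0.05 and over 2-fold. This test compares libraries, and no test between conditions exists in this series. Log2 ratios are replicate 2 over replicate 1 of TMM-scaled counts with a prior count of 0.5.

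The 26 gene lists covered steroid synthesis, cortical identity, the cortical zones and X-zone, chromaffin cells, stroma, endothelium, glia, leukocytes, erythroid cells, adipocytes, kidney, liver, pancreas, skeletal muscle, gonad, and cell programmes. They, the tests, the alternatives and the rule for named genes were fixed before the data were examined. A list's level is the median over members of mean TPM, set among 10000 random lists of its size from genes above 0 TPM. Its difference is the median log2 ratio of members at 1 TPM or more, set among 10000 random lists matched in 20 bins of mean TPM. Percentiles describe these libraries only. Bootstrap intervals of a list's difference are 95% intervals over 2000 draws of its members at 1 TPM or more. They cover the spread over genes and not that between animals. The random lists for levels also drew on genes below the detection level, so a list of ordinarily expressed genes ranks high too. The liver and skeletal muscle lists reached percentile 100 as well, so a high percentile does not set a gene group apart as typical of the gland. Named genes were the 15 highest nuclear and 3 highest mitochondrial genes, the 4 highest members of each list, all steroid synthesis genes and those of 5 fixed ratios. Also named were up to 10 genes each way past the binomial test, over 2-fold and at 5 TPM in both quantifications, list genes with different main transcripts, the 5 genes furthest apart each way between the tables, and members where a count of 5 or fewer is given. Some genes that this rule takes in are not analysed here. Another 5 lists were added after the data were seen.

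The binomial step was tested on simulated Poisson counts for the 18160 genes, with 200 genes changed. It called 47 of 50 genes raised and 43 of 50 lowered by 1.5 on the log2 scale, 50 of 50 and 47 of 50 at 2, and 1 of 17960 unchanged genes. The simulated counts held counting error only, so these numbers do not cover calls that arise from spread between animals. A simulated coefficient of variation of 0.2 over 18160 genes was estimated as 0.200. All genes were simulated with this same value, so that test does not cover data whose genes differ in spread. Of 200 random lists of 10 among 15123 genes, 3.5% lay outside the central 95% of matched lists, and 100% lay above it once shifted by 0.5. Lists of genes that vary together were not simulated. Alternatives were DESeq2 1.42.0 size factors and dispersions, total counts and spike-ins as sizes, other filters and pseudocounts, the alignment-free table, rescaled TPM and each library alone. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Windows of 100 bases of Akr1c18 and Cyp11b2 transcripts were compared with the M21 transcripts of all other genes, allowing 2 mismatches. Known spike-in concentrations and strand-specific signal tracks were not used here.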

Results

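Total RNA was profiled in the adrenal gland of newborn mice, the paired organ whose cortex makes steroid hormones and whose medulla makes catecholamines. The animals were 4-day-old B6CASTF1/J males, an F1 hybrid between the laboratory strain C57BL/6J and the wild-derived strain CAST/EiJ. The series held 1 group with 2 biological replicates, from glands that the sample characteristics number as different males, and no second condition, so the comparisons were those within the gland and between the replicates. Each library was made from 300 ng of ribosomal RNA-reduced total RNA with a directional kit and ERCC spike-in transcripts. The gene tables held 32231301 expected counts on annotated genes in replicate 1 and 30292851 in replicate 2. A gene with 0 counts could therefore have made up at most 0.0931 and 0.0990 CPM, the share of gene counts that 3 counts give, and intervals and floors cover counting error only.

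Small structural RNAs and mitochondrial ribosomal RNA had the highest TPM in the gene tables. The alignment-free tables, which lack most short genes, listed Rn7s1 at 2.05 and 3.56 TPM in replicates 1 and 2 and Rmrp at 0 TPM. Rn7s1 and Rn7s2 (chromosome 12, 69159295 to 69159594 and 69361182 to 69361481 in mm10), 2 near-identical genes for the RNA of the signal recognition particle, took 30.8% ± 0.775 of all TPM (SD, n = 2) but 6.16% ± 0.336 of the counts. They were followed among nuclear genes by Rn7sk, a regulator of transcription elongation, at 58083 ± 3544 TPM, and by Gm26917, annotated as a lincRNA, at 19230 ± 321 TPM. Gm26917 and its neighbour Gm42418, also annotated as a lincRNA, together took 5.70% of the counts, out of 7.28% for all lincRNA genes. What these reads come from was not tested. The other nuclear genes among the 15 highest included Rpph1 and Rmrp, RNA parts of processing ribonucleases, and Gm42418, next to Gm26917 on chromosome 17. They also included the chromosome 1 genes Gm28661, Gm10925 and Gm28437, annotated as unprocessed pseudogenes, and the small nuclear RNA genes Gm23472, Gm23444, Rnu2-10, Gm23849 and Gm23971. Reads of such copies cannot be assigned with certainty, and Rnu2-10, Gm23849 and Gm23971 carried the same 4023 ± 399 TPM, as did Gm24950, so the limit of 15 falls within a tie. The 3 highest mitochondrially encoded genes in the gene tables were mt-Rnr2 at 35058 ± 955 TPM, mt-Rnr1 at 26654 ± 1761 TPM and mt-Co1 at 6653 ± 52.8 TPM. Nuclear copies can exchange reads with mitochondrial genes, so both rankings are uncertain for such genes. For example, mt-Co2 was listed far lower in the gene tables than in the alignment-free tables. Protein-coding genes took 72.9% ± 0.941 of the counts and 37.9% ± 1.87 of TPM, so TPM of messenger RNAs is low on this scale. At a mean TPM of 1 or more, 15123 genes were detected, among them 13305 of 22028 protein-coding genes and 206 of 5854 lincRNA genes.

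Messenger RNAs for steroid synthesis stood among the most abundant of the gland. Hsd3b1 (ENSMUSG00000027871.16, chromosome 3, 98852194 to 98859794), an enzyme that turns pregnenolone into progesterone, reached 2955 ± 676 TPM (SD, n = 2). Cyp21a1, the steroid hydroxylase that acts on progesterone, followed at 1884 ± 431 TPM. Cyp11a1, which cleaves the side chain of cholesterol, stood at 882 ± 73.7 TPM and Star, which carries cholesterol into mitochondria, at 827 ± 51.8 TPM. Cyp11b1, the enzyme of the last step to corticosterone, had 776 ± 159 TPM. The electron carriers Fdx1 and Fdxr had 371 ± 46.6 and 232 ± 23.5 TPM, and Por 64.1 ± 4.55 TPM. Lower levels were found for Hsd3b6 (17.1 ± 1.92 TPM), Srd5a1 (5.81 ± 0.339 TPM) and Hsd11b2 (1.55 ± 0.346 TPM). Cyp17a1, needed for cortisol and androgens, had 0.495 ± 0.00707 TPM from 30 and 22 counts, and its log2 ratio to Cyp11b1 was -10.60 ± 0.28. The list of 13 steroid synthesis genes had a median of 232 TPM, above all 10000 random lists of its size, with 12 members at 1 TPM or more. Among nuclear protein-coding genes, chosen for mention after their values were seen, only Eef1a1, an elongation factor of translation, came between Hsd3b1 and Cyp21a1, at 2698 ± 141 TPM.

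Genes of adrenocortical identity and of each cortical zone were present together. The 14 genes of cortical identity and ACTH response had a median of 54.4 TPM, and all 14 passed 1 TPM. Scarb1, the receptor for high-density lipoprotein, had 229 ± 5.06 TPM, Soat1, which esterifies cholesterol, 208 ± 10.4 TPM, Nr5a1, the transcription factor of steroid-producing cells, 158 ± 3.87 TPM, and Mrap, the accessory protein of the ACTH receptor, 94.3 ± 18.2 TPM. The 13 genes of the zona glomerulosa, the aldosterone-producing outer zone, had a median of 21.9 TPM (percentile 99.94 among random lists), led by the potassium channel gene Kcnk3 at 276 ± 29.2 TPM, Dab2 at 166 ± 3.44 TPM, Cyp11b2 at 107 ± 52.3 TPM and the angiotensin receptor gene Agtr1a at 60.0 ± 3.88 TPM. The 7 genes of the zona fasciculata, the corticosterone-producing zone, had a median of 94.4 TPM (percentile 99.99). They were led by Cyp11b1, Fdx1, Scarb1 and Mrap. Cyp11b1 and Fdx1 are also on the steroid synthesis list, and Scarb1, Mrap and Mc2r on that of cortical identity. The level of this list is therefore not separate evidence for the zone. Cyp11b1 exceeded Cyp11b2, the gene of aldosterone synthase, by a log2 ratio of 2.62 in replicate 1 and 3.24 in replicate 2, a mean of 2.93 ± 0.44 (SD, n = 2). The genes lie side by side on chromosome 15 (74834125 to 74841643 and 74851010 to 74856318) and are similar in sequence, and without length scaling the log2 ratio was 3.94.

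The X-zone, a transient inner zone of the mouse cortex of fetal origin, was represented by Akr1c18, a hydroxysteroid dehydrogenase gene (ENSMUSG00000021214.14, chromosome 13, 4132615 to 4150654), at 275 ± 166 TPM, Cyp2f2 at 64.3 ± 16.9 TPM, Thrb, a thyroid hormone receptor gene, at 16.03 ± 1.09 TPM and Pik3c2g at 0.780 ± 0.156 TPM. The list's median was 40.1 TPM (percentile 99.2). Akr1c18 stood below Cyp11b1 by a log2 ratio of -1.18 in replicate 1 and -2.07 in replicate 2, so this ratio differed between the glands more than any of the other 4 fixed ratios.

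**Figure D1:**
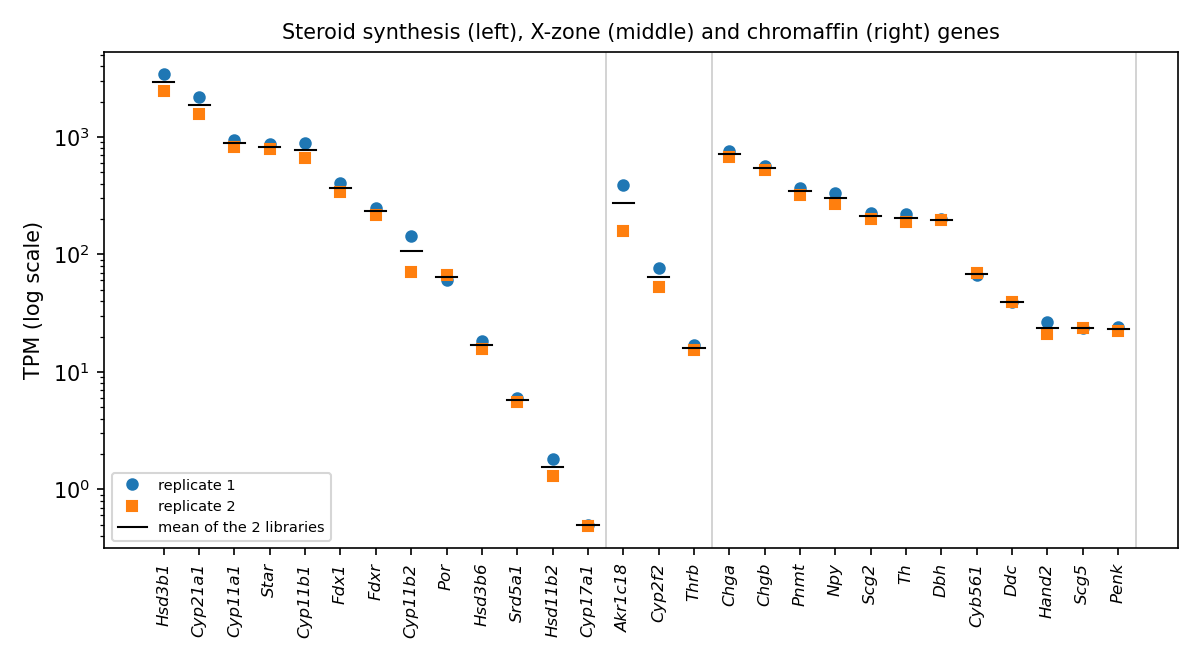
TPM on a log axis of the 13 steroid synthesis genes (left), the 3 highest X-zone genes (middle) and the 12 highest chromaffin genes (right); circles and squares are replicates 1 and 2 and the bar is their mean. Akr1c18 (393 and 158 TPM) and Cyp11b2 (144 and 70.4 TPM) are the genes whose replicates lie over 2-fold apart.

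Genes of the medulla were also present. All 25 chromaffin genes passed 1 TPM, with a median of 20.2 TPM that exceeded all 10000 random lists. Chga and Chgb, which encode proteins of the catecholamine granules, had 719 ± 54.8 and 541 ± 31.8 TPM, Pnmt, which makes adrenaline from noradrenaline, 344 ± 34.3 TPM, and Npy, a neuropeptide gene, 301 ± 45.3 TPM. Th, the rate-limiting enzyme of catecholamine synthesis (chromosome 7, 142892752 to 142931128), had 204 ± 20.6 TPM. The log2 ratio of Th to Pnmt was -0.75 ± 0.0017 and that of Cyp11a1 to Th 2.11 ± 0.02 (SD, n = 2), so these ratios were nearly the same in both glands.

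Genes of supporting cell types were also found. The median of the 15 capsule and stroma genes was 17.8 TPM (percentile 99.8), led by the collagens Col3a1 (344 ± 69.3 TPM), Col1a1 (313 ± 106 TPM) and Col1a2 (244 ± 64.3 TPM) and by Postn (138 ± 36.6 TPM). The 13 endothelial genes had a median of 26.7 TPM, above all random lists, led by Egfl7, Plvap, Cdh5 and Pecam1 at 84.7 ± 13.3, 64.3 ± 1.56, 38.4 ± 4.39 and 36.9 ± 4.65 TPM. The 15 leukocyte genes had a median of 11.4 TPM (percentile 98.2). The macrophage genes Lyz2, C1qb, C1qa and C1qc led at 22.8 ± 5.25, 20.2 ± 1.44, 18.98 ± 0.933 and 16.9 ± 0.686 TPM. The 9 Schwann and sustentacular genes had a median of 3.95 TPM (percentile 75.4) and included Fabp7 (7.32 ± 2.5 TPM) and Mbp (6.60 ± 1.82 TPM).

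Genes of neighbouring tissues and of blood were also found. Erythroid genes had a median of 19.1 TPM (percentile 99.6), which was 11.5 TPM in replicate 1 alone and 24.8 TPM in replicate 2 alone, with the adult globins Hba-a1, Hbb-bs, Hba-a2 and Hbb-bt at 1233 ± 511, 1140 ± 479, 829 ± 348 and 174 ± 64.1 TPM. The embryonic globins Hbb-y, Hbb-bh1 and Hba-x had 0 counts in both libraries. Adipocyte genes had a median of 31.2 TPM (percentile 99.99), led by Fabp4 (378 ± 40.6 TPM), Plin1 (141 ± 7.30 TPM), Ucp1, the uncoupling protein of brown fat (139 ± 49.4 TPM), and Adipoq (44.9 ± 9.02 TPM). The 8 skeletal muscle genes had a median of 74.9 TPM, above all random lists, led by Acta1, Mylpf, Myl1 and Tnnt3 at 306 ± 118, 211 ± 99.8, 126 ± 56.5 and 81.1 ± 35.0 TPM. Kidney genes had a median of 0.458 TPM (percentile 19.04), and of the 12 only Aqp1, also an endothelial water channel (21.4 ± 5.49 TPM), Slc34a1 (2.38 ± 1.61 TPM) and Lrp2 (1.14 ± 0.594 TPM) passed 1 TPM, with Aqp2 at 0.810 ± 0.566 TPM. Gonad genes had a median of 0.170 TPM (percentile 6.90), with only Insl3 (2.85 ± 0.205 TPM) over 1 TPM of a list led by Insl3, Sox9, Dhh and Amh. None of the 8 pancreas genes reached 1 TPM, their median was 0.12 TPM (percentile 3.79; 0.0600 and 0.175 TPM in replicates 1 and 2 alone), and Cpa1, Ctrb1, Ins2 and Cela2a were the highest. The male label was checked on Eif2s3y, Ddx3y, Uty and Kdm5d on the Y chromosome (37.2 ± 2.22, 29.2 ± 1.55, 14.2 ± 1.68 and 9.57 ± 0.255 TPM) and on Xist at 0.0550 ± 0.0212 TPM, for a list median of 14.2 TPM (percentile 93.5).

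Genes of growth and biosynthesis were expressed in the newborn gland. All 19 cell cycle genes passed 1 TPM with a median of 20.9 TPM, above all random lists, and Pcna, Mcm6, Mcm7 and Top2a, genes of DNA replication and mitosis, led at 46.8 ± 4.63, 33.4 ± 1.86, 32.8 ± 4.88 and 31.9 ± 3.62 TPM. The 70 replication-dependent histone genes had a median of 86.6 TPM, also above all random lists, led by Hist2h2aa2, Hist1h4h, Hist1h4k and Hist1h4f. All 21 cholesterol synthesis genes passed 1 TPM, with a median of 12.7 TPM (percentile 99.7), led by Dhcr7 (83.9 ± 25.4 TPM), Hmgcs1 (70.8 ± 5.32 TPM) and Fdps (28.9 ± 1.04 TPM). Of 30 imprinted genes 28 passed 1 TPM, with a median of 35.9 TPM, above all random lists. Gnas, Meg3, Cdkn1c and H19 led at 1102 ± 41.2, 776 ± 179, 554 ± 16.1 and 530 ± 265 TPM. The 89 ribosomal protein genes had a median of 384 TPM, above all random lists, led by Rpl41, Rps27, Rplp1 and Rps14. The abundant non-coding RNAs had a median of 1576 TPM in the gene tables and 12.4 TPM in the alignment-free tables, led in the former by Rn7sk, Rpph1, Rmrp and Malat1 (3055 ± 556 TPM). Of 37 mitochondrially encoded genes 15 passed 1 TPM, with mt-Nd1 (3631 ± 315 TPM) next after mt-Co1 in the gene tables. The others, all transfer RNA genes, were listed at 0 TPM, which set the list's median to 0 TPM (percentile 0). Such short RNAs have little or no effective length in either kind of table. Their values of 0, and the list's level, therefore do not show that they were absent. Immediate early and heat shock genes had a median of 12.4 TPM (percentile 97.4), which was 14.04 TPM in replicate 1 alone and 8.21 TPM in replicate 2 alone, led by Jun (20.3 ± 5.40 TPM), Dusp1 (16.7 ± 1.71 TPM), Junb (15.8 ± 7.83 TPM) and Ier2 (13.3 ± 1.19 TPM).

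The replicates ranked genes alike, and a set of liver genes set them apart. Across the 15123 detected genes, which are not independent replicates, Spearman's rho of log2(TPM + 1) was 0.964 and Pearson's r 0.962. Replicate 2 lay within 2-fold of replicate 1 for 95.8% of these genes, with a median absolute log2 ratio of 0.15. The biological coefficient of variation was 0.233 in edgeR over 18160 genes, and 0.0390 as the median gene-wise estimate of DESeq2. The first is 1 value shared by all these genes, the liver genes below included, and the second is a median over genes. They are therefore different measures of spread. An exact two-sided binomial test of each gene's counts, which compares these libraries and not conditions, found 6084 of 18160 genes past the adjusted threshold. At this depth, and with 1 library per animal, that number says little about which genes differ between animals. Of these, 723 genes also differed over 2-fold, 613 higher in replicate 2 and 110 higher in replicate 1. Without the filter on low counts the number was 1195.

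**Figure D2:**
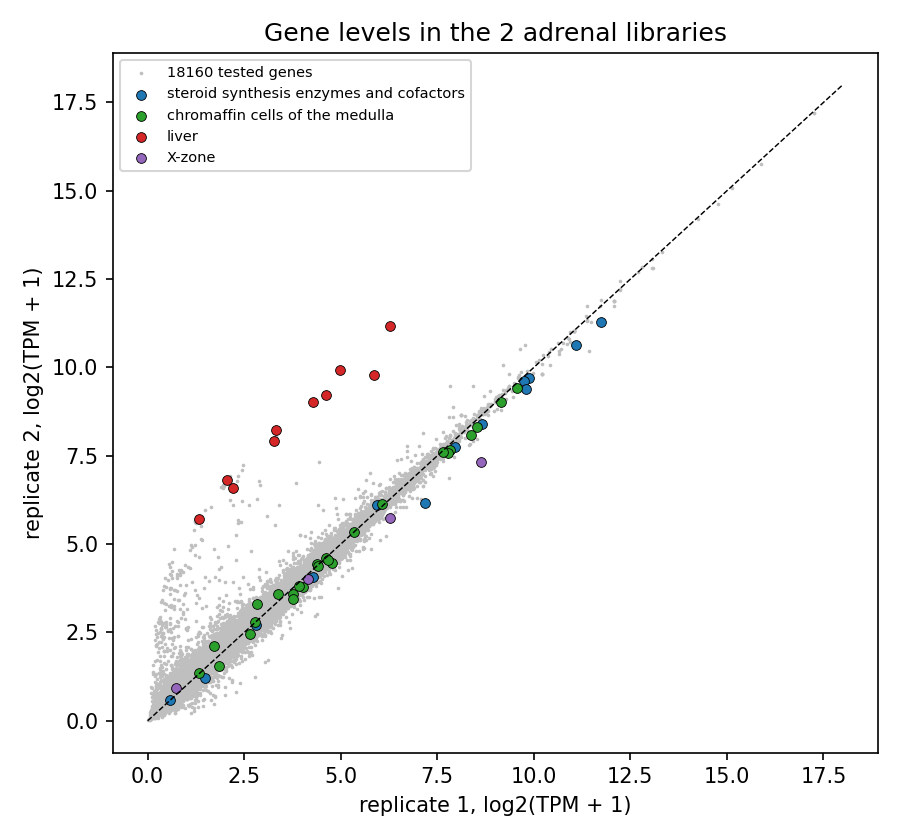
Each point is a gene, with log2(TPM + 1) in replicate 1 on the x axis and in replicate 2 on the y axis, for the 18160 tested genes (grey) and the members of 4 lists (colours); the dashed line marks equal values. The 10 liver genes lie far above the line, while most steroid synthesis and chromaffin genes lie near it.

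All 10 genes of the liver list were higher in replicate 2, with a median log2 ratio of 4.77 (percentile 100 among 10000 random lists matched on expression), or 27.3-fold, and log2 ratios between 3.99 and 5.05. Alb, which encodes serum albumin (chromosome 5, 90460897 to 90476602), had 76.3 TPM in replicate 1 and 2319 TPM in replicate 2. Ahsg, the gene of fetuin A, had 30.3 and 974 TPM, Trf, the gene of transferrin, 57.6 and 884 TPM, and Afp, the gene of alpha-fetoprotein, 23.6 and 590 TPM. The list's median was 13.8 TPM in replicate 1 and 408 TPM in replicate 2, so its level of 211 TPM (percentile 100) rests on replicate 2. The 10 highest folds in replicate 2 among genes at 5 TPM or more belonged to Apcs (43.5-fold), Azgp1 (42.8-fold), Ugt1a1 (40.1-fold), Itih1 (39.3-fold), Ces1c (36.4-fold), Slc10a1, Lipc, F12, Itih3 and Cyp2e1 (33.6-fold). They include plasma proteins such as Apcs, the serum amyloid P component, and enzymes and transporters such as Ugt1a1, which conjugates bilirubin, and Slc10a1, a bile acid transporter. At over 8-fold, a level chosen after the data were seen, 178 genes were higher in replicate 2 and 1, Tmem52b at a log2 ratio of -3.07, was higher in replicate 1. Those 178 genes took 0.0705% of the gene counts of replicate 1 (95% Wilson interval 0.0696 to 0.0714) and 1.65% of those of replicate 2 (1.65 to 1.66). They were chosen by fold from these same counts, which the intervals do not cover, and were not assigned to a tissue.

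Other groups higher in replicate 2 differed by far less than the liver genes. The 8 erythroid genes over 1 TPM were all higher in replicate 2, with a median log2 ratio of 0.79 (percentile 100), though only Slc4a1, an anion exchanger of red cells, passed the test and 2-fold. The 8 skeletal muscle genes had a median of 0.79 (percentile 100), and Myh3, the embryonic myosin heavy chain, was the only one past the test and 2-fold, at a log2 ratio of 1.87. Schwann and sustentacular genes had a median of 0.39 (percentile 99.4). Small positive medians were found for adipocytes (0.15, percentile 99.2), histones (0.14, percentile 100), capsule and stroma (0.14, percentile 99.9), the cell cycle (0.12, percentile 99.9), cholesterol synthesis (0.12, percentile 99.6), leukocytes (0.10, percentile 93.2), imprinted genes (0.08, percentile 99.8), the endothelium (0.05, percentile 96.5) and the sex label genes (0.01, percentile 69.6, and -0.01 in the alignment-free table). Slc22a18 of the imprinted genes passed the test and 2-fold with a log2 ratio of 1.17, and Lep of the adipocytes with -1.10. Igf2 and H19, imprinted growth regulators, had log2 ratios of 0.92 and 0.98, under 2-fold. Ribosomal protein genes had a median of -0.01 (percentile 97.3), which turned to 0.02 with total counts or spike-ins as library sizes, with Rps12l1 at 1.66 (and 0 TPM in the alignment-free tables) as the one past both criteria, the non-coding RNAs -0.17 (percentile 4.41, and 0.28 in the alignment-free table), and Insl3 as the only gonad gene compared 0.06 (percentile 50.6, and -0.10 in the alignment-free table). Mitochondrially encoded genes had a median of -0.11 (percentile 9.19), with a bootstrap interval of -0.140 to 0.087. The one past both criteria, mt-Co2, had 43.0 and 93.0 TPM in the gene tables and 1040 and 958 TPM in the alignment-free tables, where its log2 ratio was -0.14.

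**Figure D3:**
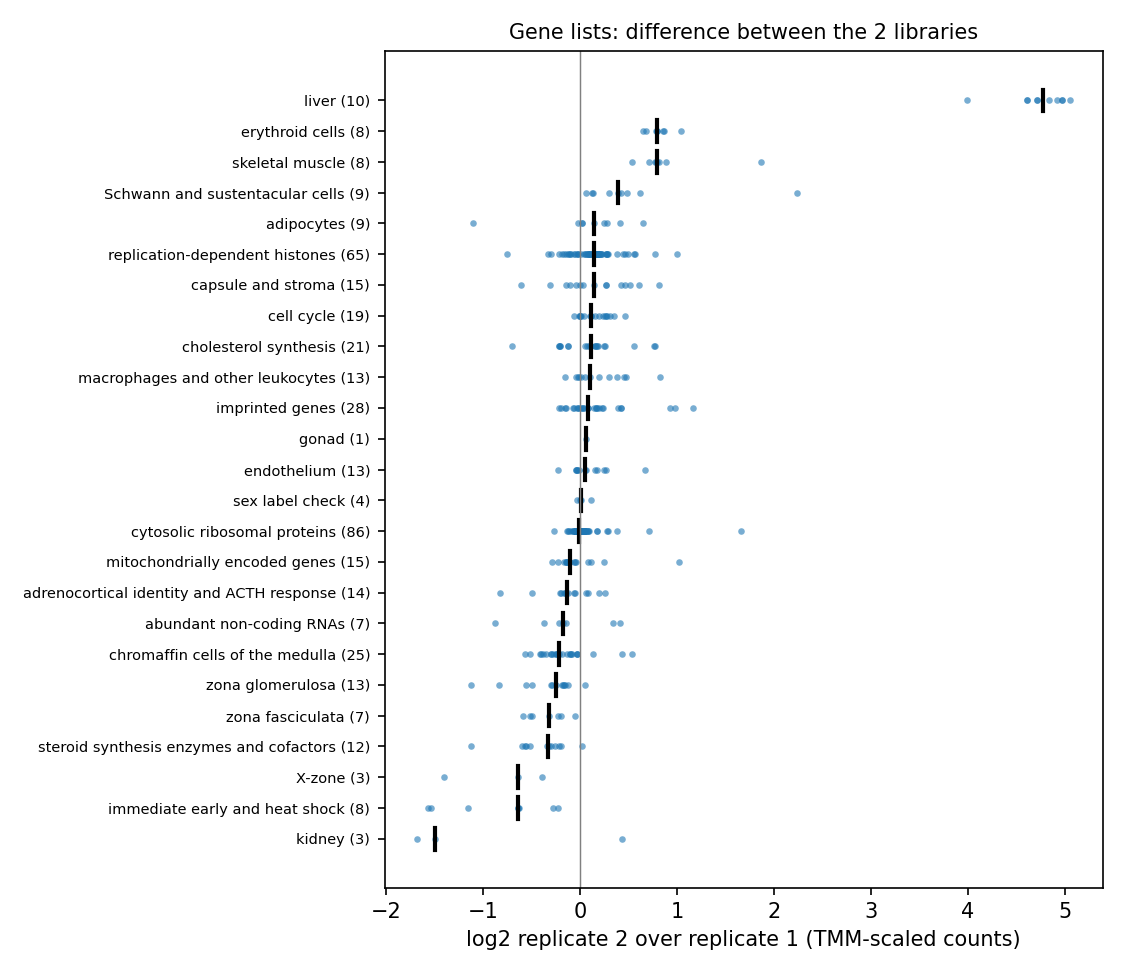
Points are genes at a mean TPM of 1 or more, by list (number of genes in brackets), and the x axis is the log2 ratio of TMM-scaled counts in replicate 2 over replicate 1; the black bar is the list's median. The liver list has a median of 4.77, and the next highest medians are 0.79.

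Steroid synthesis, X-zone and immediate early genes had negative medians, and single members of these lists were over 2-fold lower in replicate 2. The steroid synthesis list had a median log2 ratio of -0.33 (percentile 0 among matched lists), and Cyp11b2 was its only member past the test and 2-fold, at -1.13. The zona glomerulosa list had a median of -0.25 (percentile 0.05), again with Cyp11b2 alone past both criteria. The zona fasciculata list had -0.32 (percentile 0.05), the chromaffin list -0.21 (percentile 0) and cortical identity -0.13 (percentile 2.95), none with a member past both. The cortical lists share genes, so their medians are not independent. The bootstrap interval of cortical identity included 0 (-0.184 to 0.015), while those of the zona fasciculata and chromaffin lists lay below 0. These intervals treat a list's genes as independent and do not measure the spread between animals. The X-zone list had -0.63 (percentile 0.02), and Akr1c18 passed both at -1.40, from 393 TPM in replicate 1 and 158 TPM in replicate 2. Immediate early and heat shock genes had -0.64 (percentile 0), with Egr1 (-1.57), Fos (-1.54), Junb (-1.16) and Fosb (-1.02), transcription factors induced within minutes of a stimulus, past both. The kidney list had -1.496 over its 3 compared genes (percentile 0.03), and Slc34a1, Lrp2, Aqp2, Slc12a1 and Slc12a3 were lower in replicate 2 by the test and over 2-fold, while Aqp1 had a log2 ratio of 0.44. In the alignment-free tables Slc12a3 had -0.30 and Fosb -0.87, under 2-fold. At 5 TPM or more, 8 genes were over 2-fold lower in replicate 2 in both quantifications. These were Egr1, Akr1c18, the retinal dehydrogenase gene Aldh1a1 (-1.31), Junb, the heat shock gene Hsph1 (-1.15), Cyp11b2, the oxytocin receptor gene Oxtr (-1.09) and Gm36723 (-1.06). In every list the number of genes past both criteria was the same when p was adjusted over the list alone.

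The transcript tables named the same main transcript for most genes but placed genes on different TPM scales. Of 9338 genes at 5 TPM or more with at least 2 annotated transcripts, 75.0% (95% Wilson interval 74.1 to 75.8) had the same main transcript in the alignment-based and the alignment-free table. Of 9 such steroid synthesis genes 7 had the same one, and of 17 chromaffin genes 15. Hsd3b1 was led by transcript Hsd3b1-201 in the alignment-based table, with 64.7% of the gene's TPM, and by Hsd3b1-202 in the alignment-free table, with 64.3%. Star-201 held 50.05% in the alignment-based table and Star-202 held 57.6% in the other. Ddc, which makes dopamine, was led by Ddc-202 with 61.2% in the alignment-based table and by Ddc-210 with 84.2% in the other. Cartpt, a neuropeptide gene, was led by Cartpt-201 with 75.5% and by Cartpt-202 with 53.2%.

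At the gene level, Spearman's rho between the tables was 0.886 across 17891 genes at 1 TPM or more in either. Of these, 7496 differed over 2-fold, 6770 of them higher in the alignment-free table. With both tables rescaled to protein-coding genes, an alternative added after the data were seen, 469 of 14922 genes differed over 2-fold and rho was 0.980. At least 3-fold apart at 5 TPM or more, 605 genes were higher in the alignment-free table and 370 in the alignment-based one. The 5 highest folds of the first kind, Gm28439, Gm47283, Hist1h2ba, Gm22567 and Gm47571, were listed at 0 TPM in the gene tables. The 5 of the second kind, Rmrp and the small nuclear RNA genes Gm23472, Gm23444, Gm24950 and Gm23971 (the last 2 tied with other copies), were listed at 0 TPM in the alignment-free table. Genes whose longest transcript was under 300 bases kept under 10% of their counts there in 190 of 190 cases, against 8 of 13831 genes of 2000 bases or more.

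**Figure D4:**
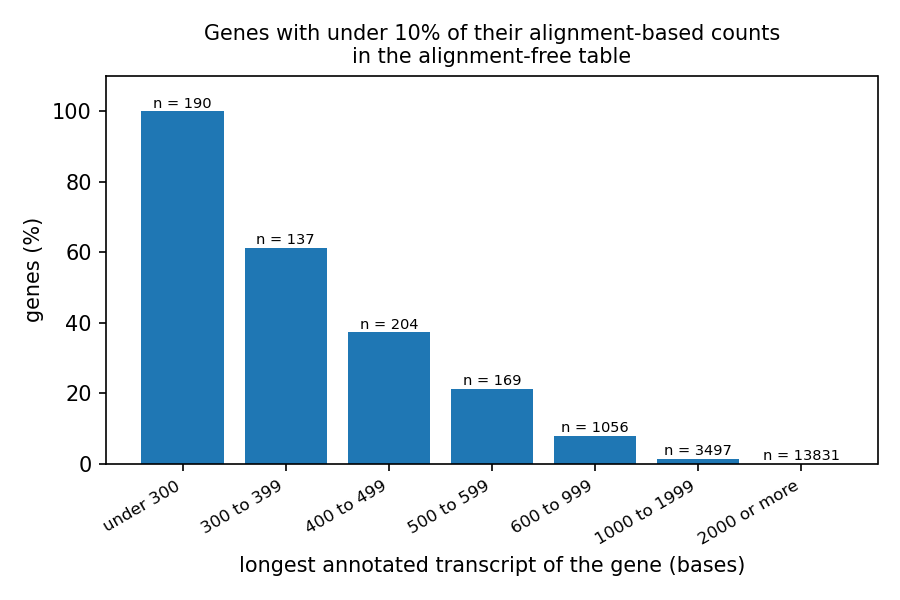
Bars give the percent of genes, by the length in bases of their longest annotated transcript (x axis), whose counts in the alignment-free table are under 10% of those in the alignment-based table, for genes with 20 or more counts over both libraries; n is the number of genes. The percent falls from 100% under 300 bases to 0.0578% at 2000 bases or more.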

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

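Of the 96 spike-in transcripts, which the main comparisons did not use, 56 had more than 3 counts in both libraries, above the limit that a count of 0 allows. They summed to 345420 and 324846 counts, 1.06% of each library. At 100 or more counts in both libraries, 31 transcripts had a median log2 ratio of replicate 2 over replicate 1 of -0.09 (SD 0.10 over transcripts), against -0.06 for the TMM library sizes. No explanation was tested for these values.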

How the results depend on the processing

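No paired analysis was possible because the series holds 1 group, so no replicate number is shared between groups. All alternatives were fixed before the data were examined except those said to be added. Spearman's rho between replicates was 0.937 with no filter and 0.941 at 10 TPM or more. The coefficient of variation was 0.233 from edgeR's common dispersion and 0.0390 from the median gene-wise dispersion of DESeq2. These are different statistics, and how much of the gap this accounts for was not tested. The 723 genes over 2-fold became 1195 without a filter, where 28783 genes were tested, and 179 at over 8-fold (added). With DESeq2 sizes, total counts, spike-in sizes and the alignment-free table they numbered 723 to 755. Total counts and spike-in sizes shifted list differences by 0.03. In the alignment-free table the median TPM was 428 for steroid synthesis, 36.0 for the zona glomerulosa, 220 for the zona fasciculata, 75.9 for the X-zone and 39.4 for chromaffin cells. Rescaled without mitochondrially encoded genes, genes annotated as rRNA and spike-ins, it was 259, 24.4 and 22.6 for steroid synthesis, glomerulosa and chromaffin genes. Rescaled to protein-coding genes (added), it was 615, 57.8, 250.4, 107 and 53.4 for these 5 lists in the first order, and 539 for liver. These rescalings multiply TPM within a library by 1 factor. The first of them left in unprocessed pseudogenes such as Gm28661 and the lincRNA genes Gm26917 and Gm42418. Chromaffin genes had 20.2 TPM without replicate 2 and 20.5 without replicate 1, and liver genes 13.8 and 408. Of the list differences, 119 stayed within the bootstrap interval and 6 moved. Of the list levels 65 moved by over 1 SD of the list's medians in the libraries, a spread that hides large shifts where the libraries differ, as for liver. The genes of highest fold, chosen for passing in both quantifications, stayed over 2-fold. Detected genes numbered 14375 to 18294 against 15123. Insl3, the only gonad gene compared, had 0.0583 with DESeq2 sizes, 0.0895 with total counts, 0.0877 with spike-ins and -0.10 in the alignment-free table, and ribosomal protein genes, at -0.01, 0.0242 with total counts and 0.0224 with spike-ins. The log2 ratio of Cyp11b1 to Cyp11b2 was 3.94 from expected counts and 3.65 from alignment-free counts (added), without length scaling in either, and stayed above 0 throughout. Main transcripts were the same for 71.4% of genes at 20 TPM, and for 74.1% without replicate 1 and 74.9% without replicate 2. Genes over 2-fold apart between the tables numbered 4005 at 10 TPM and 469 for protein-coding genes (added), the first among fewer genes. The second also rescaled TPM in both tables, and its median log2 difference was -0.10 against 0.91. With 2 libraries, depth limits only low genes, and the spread between animals rests on 1 difference per gene.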

Other observations

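Gene groups that the report did not describe were looked at after the data were seen. Of 39 Hox genes, which mark position along the body axis, 22 passed 1 TPM, led by Hoxb9 (34.9 ± 6.29 TPM, SD, n = 2), Hoxb8 (22.6 ± 2.76 TPM), Hoxb6 (17.3 ± 2.62 TPM) and Hoxb7 (16.8 ± 3.94 TPM). Hoxa13, Hoxb13, Hoxc13 and Hoxd13, the most posterior members, were listed at 0 TPM. Their median was 2.15 TPM (percentile 71.7) and their median log2 ratio of replicate 2 over replicate 1 was -0.11 (percentile 2.35), and Hoxa10, at -2.42, was the only one past the binomial test and 2-fold. The 13 antioxidant genes had a median of 107 TPM, above all random lists, led by Sod1 (425 ± 34.2 TPM) and Gpx4 (229 ± 12.1 TPM), and a median log2 ratio of -0.05 (percentile 42.7).

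All 10 circadian clock genes passed 1 TPM, with a median of 15.7 TPM (percentile 99), led by Per1 (41.3 ± 6.80 TPM), Dbp (35.3 ± 14.5 TPM), Nr1d1 (32.0 ± 12.5 TPM) and Cry2 (21.1 ± 3.19 TPM). Their median log2 ratio was 0.24 (percentile 99.98), with Dbp at 0.83, Nr1d1 at 0.71 and Arntl, which is expressed in the opposite phase, at -0.55, all under 2-fold. Of 13 neuropeptide genes, Adm (10.1 ± 0.247 TPM), Gal (3.19 ± 0.0566 TPM) and Nmb (1.33 ± 0.898 TPM) passed 1 TPM. That list's median was 0.150 TPM (percentile 3.37) and its median log2 ratio -0.05 (percentile 31.6), with Nmb past the test and 2-fold at 1.22 (0.79 in the alignment-free tables). The last list, 16 enzymes of hepatocytes that are not secreted, had a median of 4.24 TPM (percentile 82.3) that rests on replicate 2 (0.565 TPM in replicate 1 and 7.78 TPM in replicate 2) and, over the 15 genes above 1 TPM, a median log2 ratio of 4.09 (percentile 100), with 14 genes past the test and 2-fold. In these lists too the numbers were the same adjusted over the list alone.

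Of the tests that follow, only the one on hepatocyte enzymes was set before its result was seen. The liver genes of replicate 2 may come from liver tissue carried with the gland. The 10 genes, all above 1 TPM in replicate 1 too, were higher by about 1 factor, with an SD of 0.306 over genes around a median log2 ratio of 4.77, and Alb, the most abundant, had 2319 TPM against 76.3. All 16 hepatocyte enzymes had a median log2 ratio of 3.90, with 14 over 3 and Fah (0.27) and G6pc (1.73) below. More blood in the gland is argued against by the erythroid genes, whose median log2 ratio was 0.79. Reads of a liver library assigned to this one would give the same median of 4.77 and cannot be told apart from tissue, since no liver library is among the tables.

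Akr1c18 and Cyp11b2 were lower in replicate 2 by log2 ratios of -1.40 and -1.13. Dilution of the gland by other tissue could lower them only along with the other cortical genes, and the 14 adrenocortical genes had a median of -0.13 (SD 0.27 over genes), far from such a fall. Reads split between near-identical copies are argued against for Akr1c18, as 0% of the 100-base windows of its transcripts were held by another gene's transcript with at most 2 mismatches. For Cyp11b2 the share was 17.4%, all with Cyp11b1, below the 54.2% of reads that its fall means, and since coverage along the transcript was not used here, such a split stays open in part. No biological explanation was tested, and a difference between the animals stays open.

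Short genes were lacking in the alignment-free table. One candidate explanation is that transcripts shorter than the assumed fragment are not counted, since 100% of the 190 genes under 300 bases kept under 10% of their counts, and the table's effective lengths imply fragments of about 326.1 and 324.1 bases. Reads shared with other copies are argued against as the whole cause, since 52 of these genes had a posterior SD of their deposited counts of 0 in both libraries, so no read was shared, and 100% of them lost their counts too. No biological explanation was tested, and both tables come from the same libraries.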
